A study of Mus musculus with 20 samples.

How the data were processed

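Whole retina of C57BL/6J background mice of 5 genotypes was profiled by RNA sequencing at P2 and P21, in 2 samples per genotype and age, each pooled from 2 retinas. The groups were taken from the sample titles. Each age had a table of its own, and within a table each gene had 1 RefSeq transcript identifier, a value per sample, a mean per genotype and the authors' comparisons of pairs of genotypes. The sample values are FPKM per the file headers, rounded by the authors to 1 decimal, and the genotype means are the authors' means of 2 samples. The comparison columns hold the authors' adjusted p values (p_value) and the authors' fold changes on a log2 scale, in which 15 and -15 stand for a ratio with a group at or near 0. DESeq is the one tool the labels name, with its version not stated. The aligner, the read counter, the genome build used for alignment and the annotation release are not given in the sources used here. FPKM divides each count by transcript length and by the mapped reads of the library, so read counts cannot be recovered from it. The depth of each sample is therefore unknown, no counting interval was computed, and genes below 1 FPKM are limited by the rounding.

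Both tables were checked before use. There were 566 genes at P2 and 1497 at P21. Every one of them had at least 1 of the authors' comparisons with an adjusted p under 0.05, a log2 fold change of at least 1 in either direction and a mean of at least 2 FPKM in 1 of the genotypes compared. The tables are thus selected on the outcome, the unchanged part of the transcriptome was not analysed here, and shares of called genes describe the selected genes alone. Selection also weakens any rescaling that assumes most genes to be unchanged. The difference between the authors' fold changes and the ratio of mean FPKM was close to constant within a comparison (SD over genes of at most 0.04 on the log2 scale), which gives the scaling the authors applied before their test. Symbols were replaced by the current symbol of the transcript for 7 genes at P2 and 19 at P21, and positions are from the RefSeq genes of GRCm38.

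The fit used log2(FPKM + 1). limma (version 3.58.1, R 4.3.3) was fitted to the 10 samples of each age with 1 term per genotype, with a variance trend on the mean and empirical Bayes moderation. There were 5 residual degrees of freedom, to which moderation added 2.95 at P2 and 3.06 at P21. At each age 7 comparisons were made, 4 of a mutant with wild type and 3 among CrxRip/+, CrxRip/Rip and Crx-/-, 14 in all. P values were two-sided and adjusted by Benjamini-Hochberg over the genes of the table, separately for each comparison, and a gene was called at an adjusted p under 0.05. Because the genes had been selected for differences in these same samples, the share of false calls at this threshold is not known. An exact permutation test of 2 against 2 samples cannot go below p = 0.33 (two-sided), so calls rest on the spread that limma pools over genes and genotypes. Ages were not tested against each other. Replicate numbers were checked as a possible pairing. The correlation across genes between deviations of the same number in different genotypes lay between -0.30 and 0.33, so the numbers were not used to pair samples.

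Gene groups were 19 hand-written lists of marker and function genes. They cover photoreceptor transcription factors, rod, cone and shared photoreceptor genes, bipolar, horizontal, amacrine and ganglion cells, Müller glia, gliosis and stress, microglia and immune genes, cell death, progenitor and cell cycle genes, RPE and pigment genes, vascular, erythrocyte, lens crystallin, immediate early and sex-linked genes. No member of the sex-linked list was in either table. For each list the called members were counted with p adjusted over the table and over the list alone. Lists with at least 3 members were tested with camera at a preset correlation of 0.01, again with a correlation estimated from the samples, and with fry, and adjusted by Benjamini-Hochberg over the 35 tests at P2 and the 105 at P21. Camera asks whether a list moved more than the rest of the table, and fry whether its genes moved one way on balance.

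Genes were named by a rule. It takes the photoreceptor transcription factors, then, per comparison with wild type, the 5 called genes with the largest rise and the 5 with the largest fall among those with a group mean of at least 5 FPKM and both mutant samples on one side of both wild-type samples. Per list it takes up to 4 called members with the largest change and up to 2 uncalled members with the highest mean, and per comparison between mutants 3 genes each way. A subset of these is given, a few genes are not reported here, and rule genes whose call changed between alternatives were mostly left to the counts. Cngb3 in CrxRip/+ and CrxRip/Rip, Gngt2 in CrxRip/Rip, Ccdc136 and Gnb3 in Crx-/- and Stat3, all at P21, were outside the rule and were chosen after their values were seen, as were the genes of the closing observations.

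The code was tested on simulated data in which known genes were changed. With a log2 change of 0.5, 1 and 2 the fit recovered 79.0, 95.7 and 98.6 percent at P2 and 64.0, 92.1 and 100.0 percent at P21, and it called 4 of 366 unchanged genes at P2 and 5 of 1297 at P21. Camera called 50 of 50 shifted lists and 2 of 50 unshifted ones at each age. The simulated genes varied independently of each other, whereas the photoreceptor lists had estimated correlations of 0.19 to 0.56 at P2. The rate of false list calls in the simulation thus does not carry over to those lists. The simulation also gave a gene the same spread in every genotype and selected no gene on its outcome. Its rates of recovered and falsely called genes thus do not carry over to the real tables, and it checks the code alone.

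Alternatives changed 1 choice at a time. They were a pseudocount of 0.1 or 5, genes with a mean of at least 5 FPKM, samples rescaled by the median of ratios, a fit of only the 2 genotypes compared, the replicate number as a block, limma array weights, a 2-fold minimum beside the adjusted p, and leaving out each sample of a comparison in turn. One more, moving the samples to the scaling of the authors' fold changes, was added after the data had been seen. Explanations were tested with GC content and length of GENCODE transcripts, pseudogene sequences and 10000 random gene lists (Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9. The authors' comparisons of Nrl-/- with the other mutants were not repeated, and their p values were used only to describe how genes had been selected.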

Results

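RNA from whole mouse retina was sequenced at postnatal day 2 (P2), when rods are still being born, and at postnatal day 21 (P21), when the photoreceptor layer is formed. 5 genotypes were compared at both ages. Besides wild type these were CrxRip/+ and CrxRip/Rip, with 1 or 2 copies of CrxRip, a dominant allele of the photoreceptor homeobox gene Crx, then Crx-/-, which lacks Crx function, and Nrl-/-, which lacks the leucine zipper factor that directs photoreceptor precursors to the rod fate. Each genotype and age had 2 samples, each pooled from 2 retinas, which makes 20 samples in 10 groups. There were 566 genes in the P2 table and 1497 in the P21 table, with 198 genes in both. Values were FPKM, counts of fragments divided by transcript length and by the mapped reads of the library, so the read depth behind each value is unknown. The summed FPKM of the P21 table was 55335.3 and 53395.9 in the wild-type samples, and it lay between 21569.4 and 40702.0 in the mutants. At P2 the sums ran from 4168.3 to 5777.3.

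Every gene of both tables had passed the authors' own threshold in at least 1 of their comparisons, so all counts below are counts among genes already selected for a difference. Group values are mean FPKM ± SD with n = 2. Changes are differences of log2(FPKM + 1), which understate the fold of genes with low FPKM. Of 352 called changes of single genes named in the text, 39 moved by more than 1.5 times with 0.1 in place of the added 1, and all of them stayed called. A gene was called when its limma p, adjusted by Benjamini-Hochberg over the genes of the table, was under 0.05. The genes had been selected on these same samples, so the adjusted p does not fix the share of false calls. Gene groups are lists fixed before the data were examined, and list members that are missing from a table were not analysed here.

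Each gene stood for 1 RefSeq transcript, placed here on genome build GRCm38. Nrl (NM_008736, chromosome 14, 55518978 to 55524981), the gene targeted in 1 of the mutants, was read first in each sample. The tables of the 2 ages were scaled separately, so no test was made across them. In the Nrl-/- retina it was at 0.1 ± 0 FPKM at P2 and 0.2 ± 0 FPKM at P21, against 75.2 ± 8.2 and 447 ± 27.2 in wild type. Crx (NM_007770, chromosome 7, 15865947 to 15879955) was in the P21 table only, at 347 ± 4.81 FPKM in wild type, 293 ± 25.3 in CrxRip/+, 196 ± 31.6 in CrxRip/Rip, 169.7 ± 2.47 in Crx-/- and 321 ± 29.6 in Nrl-/-. The Crx value of a whole transcript cannot tell which part of the gene was deleted or changed, so it checks neither the CrxRip nor the Crx-/- genotype.

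**Figure D1:**
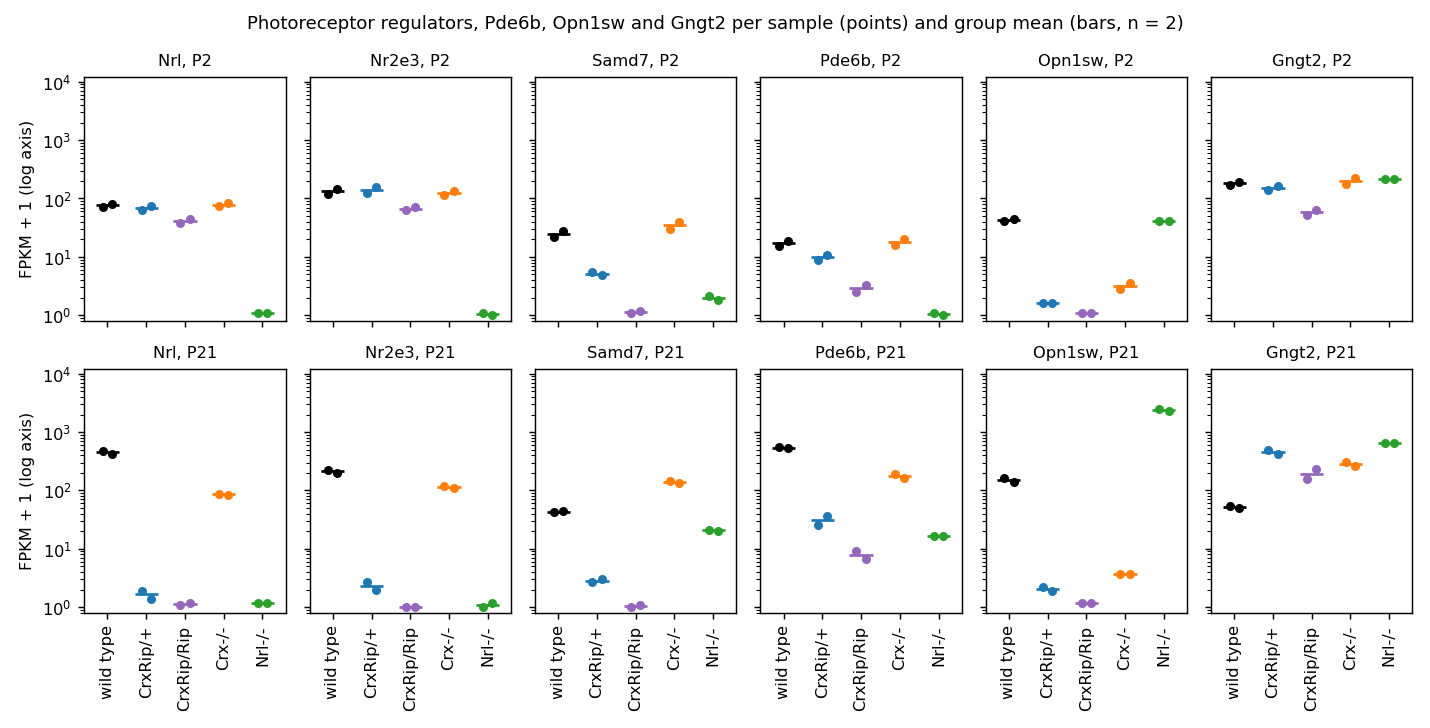
FPKM (log axis of FPKM + 1) of Nrl, Nr2e3, Samd7, Pde6b, Opn1sw and Gngt2 by genotype, with 1 point per sample, a bar at the mean of 2 samples, and P2 and P21 as separate panels. Nrl was at 0.65 ± 0.35 FPKM in CrxRip/+ at P21 and at 68.1 ± 7.14 FPKM in CrxRip/+ at P2.

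The comparison of CrxRip/+ with wild type at P2 asks what a single dominant allele does before rods and cones mature. Cone and rod transcripts were already lower in CrxRip/+ while the rod factor Nrl was at 68.1 ± 7.14 FPKM against 75.2 ± 8.2 in wild type and was not called (adjusted p = 0.621). Opn1sw, the short-wave cone opsin, fell by 4.74 (0.6 ± 0 against 41.8 ± 1.7 FPKM). Of the 10 cone genes in the table, 9 fell and 0 rose, and the counts were the same when adjusted over the list alone. Pde6h, the inhibitory subunit of the cone phosphodiesterase, changed by -2.75, and Gnat2 and Gnb3, the cone transducin alpha and beta subunits, changed by -2.23 and -1.39. Gngt2, the gamma subunit, was the uncalled member at 151 ± 18 against 181 ± 13.4 FPKM. Rod genes fell in 7 of 9, also when adjusted over the list alone, among them Cnga1, the rod channel subunit (-2.30), Pde6g, the rod phosphodiesterase inhibitor (-1.50), and Nxnl1, which encodes a rod-derived cone viability factor (-0.88). Sag, the rod arrestin, was not called (41.6 ± 3.11 against 51.6 ± 7.35 FPKM). Genes that rods and cones share fell in 10 of 16 (11 when adjusted over the list alone), with recoverin (Rcvrn) at -1.29, the retinol dehydrogenase Rdh12 at -0.82 and the guanylate cyclase activator Guca1a at -1.98. Among photoreceptor transcription factors 4 of 7 fell, over all genes and adjusted over the list alone, including Samd7, a repressor of non-rod genes (-2.28), and the cone nuclear receptor Rxrg (-0.83).

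Outside these lists, Fam19a3, which encodes a secreted chemokine-like protein, was at 0.1 ± 0 FPKM against 5.45 ± 0.35 and fell by 2.55. Moxd1, a relative of dopamine beta-hydroxylase, rose by 1.20, Nudt7, a peroxisomal hydrolase, by 0.73, and Spsb1, a ubiquitin ligase adaptor, by 0.66. The ribosomal protein gene Rpl21 (1.54) and the chromatin protein gene Hmgb1 (1.10) were higher as well, with the reservation that both have many processed pseudogenes. In all, 21 genes rose and 72 fell of 566 tested, and the largest adjusted p among the called genes named for this comparison was 0.00695 (limma). Without wild-type replicate 2 the number called was 55 instead of 93. The lists were lower than the rest of the table by camera, at adjusted p = 5.18e-11 for cone genes and 9.19e-06 for rod genes, and adjusted p = 0.176 and 0.176 with an estimated correlation. For shared photoreceptor genes and transcription factors camera gave adjusted p = 2.34e-06 and 0.00442, and adjusted p = 0.234 and 0.18 with an estimated correlation.

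In CrxRip/Rip at P2, where both copies of Crx carry the allele, the same photoreceptor groups were lower and the rod factors were lower with them. Nrl changed by -0.90 (39.9 ± 4.74 against 75.2 ± 8.2 FPKM) and Nr2e3, the nuclear receptor that silences cone genes in rods, by -0.99 (65.8 ± 6.22 against 132 ± 16.6 FPKM). Every photoreceptor transcription factor in the table was lower, 7 of 7 (the same adjusted over the list alone), with Samd7 at -4.42, the cone thyroid hormone receptor Thrb at -1.08, Rxrg at -1.32 and Ankrd33, a repressor of photoreceptor genes, at -0.62. All 10 cone genes, all 9 rod genes and all 16 shared genes fell, over the table and adjusted over each list alone. Opn1sw was at 0.1 ± 0 FPKM and Pde6h was listed at 0, against 41.8 ± 1.7 and 7.8 ± 1.13 in wild type. Gnat2 changed by -2.48 and Gnb3 by -2.41. Among rod genes Pde6g changed by -3.04, Sag by -2.72 and Pde6b, the beta subunit of the rod phosphodiesterase, by -2.56. The disc rim protein Prph2 changed by -2.45, Rcvrn by -2.61 and the potassium channel subunit Kcnv2 by -2.03.

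Nxnl2, a thioredoxin-like gene needed by photoreceptors, was at 0.4 ± 0.14 FPKM against 11.5 ± 2.69 and fell by 3.15. The largest rises among well expressed genes were in Acbd7, an acyl-CoA binding protein (2.06), Lmo2, a LIM-only transcriptional cofactor (1.86), Slitrk6, a neuronal membrane protein (1.63), and Il11ra1, the interleukin 11 receptor (1.36). Rpl21 was higher by 1.86, with the reservation on pseudogenes given above. In total 33 genes rose and 120 fell, with a largest adjusted p of 0.00184 among those named (limma). By camera the adjusted p was 1.75e-09 for cone genes, 5.90e-07 for rod genes, 1.72e-09 for shared genes and 1.19e-04 for transcription factors, and each of the 4 lists had adjusted p = 0.176 with an estimated correlation.

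The direct comparison of CrxRip/Rip with CrxRip/+ at P2 asks what the second mutant copy adds. Thrb changed by a further -0.63 (2.2 ± 0.14 against 3.95 ± 0.07 FPKM) and Samd7 by a further -2.15 (0.15 ± 0.07 against 4.1 ± 0.42 FPKM). Sag, at 7.2 ± 2.83 against 41.6 ± 3.11 FPKM, changed by -2.42, Pde6b by -1.77, Pde6g by -1.54, Prph2 by -1.77 and the cadherin Cdhr1 of the photoreceptor outer segment by -1.14. Gngt2 fell by 1.40, whereas Gnat2, already low, was at 1.15 ± 0.35 against 1.55 ± 0.07 FPKM and was not called. Rod genes were lower in 7 of 9 (8 adjusted over the list alone), cone genes in 7 of 10 (8), shared genes in 13 of 16 (14) and transcription factors in 5 of 7 (5). Slitrk6, Il11ra1 and Lmo2 rose by 1.11, 1.05 and 1.17. In this comparison 16 genes rose and 64 fell (limma, largest adjusted p of those named 0.00268), and 51 instead of 80 were called without CrxRip/+ replicate 2. With only the 4 samples of these genotypes in the fit, 43 were called. Camera gave adjusted p = 1.59e-09 for shared genes, 1.99e-06 for rod genes, 7.81e-06 for cone genes and 7.96e-05 for transcription factors, and adjusted p = 0.176 for each with an estimated correlation.

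Crx-/- at P2 asks what the loss of Crx function does at this age. Nrl and Nr2e3 were not called and a subset of photoreceptor genes was lower. Ankrd33 changed by -1.27 (1.15 ± 0.07 against 4.2 ± 0.14 FPKM) and Thrb by -0.57, the 2 called members of 7 transcription factors. The counts adjusted over the list alone were 1 higher and 2 lower. Opn1sw changed by -3.77 (2.15 ± 0.49 against 41.8 ± 1.7 FPKM), Pde6h by -1.58 and the proton channel Otop3 by -0.75, while Gnb3 was at 116 ± 9.33 against 104 ± 10.5 FPKM and was not called. Cone genes were higher in 1 and lower in 4 of 10, and rod genes were lower in 5 of 9, with the same counts adjusted over each list alone. Cnga1 changed by -1.64, Nxnl1 by -1.30 and Reep6, an endoplasmic reticulum protein of rods, by -0.78. Shared genes fell in 9 of 16 (11 lower and 1 higher adjusted over the list alone), among them Rdh12 (-1.29), Guca1a (-1.38), Kcnv2 (-1.21) and the synaptic leucine-rich protein Lrit1 (-1.43). Phosducin (Pdc), which binds transducin, was at 178 ± 20.2 against 142 ± 18.5 FPKM and the disc protein Rom1 at 84.2 ± 8.7 against 73.8 ± 11.1 FPKM, both uncalled.

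The homeobox gene Obox6, which lies 26.3 kilobases from Crx, was at 8.1 ± 0.42 FPKM in Crx-/- against 0.3 ± 0 in wild type, a rise of 2.81. Moxd1 rose by 2.20, Spsb1 by 1.16 and Lhx4, a LIM homeobox gene of bipolar cells and developing cones, by 0.67, while the photoreceptor synapse scaffold Mpp4 fell by 1.48. Altogether 52 genes rose and 117 fell, and rescaling by the median of ratios gave 86 higher and 57 lower. The largest adjusted p of the called genes named was 0.00279 (limma). The total was not stable, since it fell whichever 1 sample was left out, in fits that leave a group of 1. No single sample carried it. Camera called the shared list (adjusted p = 0.00769, adjusted p = 0.496 with an estimated correlation) and not the rod list (0.0786), the cone list (0.618) or the transcription factors (0.729).

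A direct comparison of the CrxRip genotypes with Crx-/- asks whether the dominant allele differs from absence of Crx function. At P2 Samd7 was at 4.1 ± 0.42 FPKM in CrxRip/+ against 34.1 ± 6.79 in Crx-/-, and it fell by 2.77, while Ankrd33 rose by 0.86. Cone genes were lower in CrxRip/+ in 9 of 10 (the same adjusted over the list alone), including Gnat2 (-1.64), Gnb3 (-1.55), Ccdc136, a coiled-coil gene of cones (-1.43), and Pde6c, the catalytic cone phosphodiesterase subunit (-1.60). Rod genes were lower in 4 of 9 and shared genes higher in 4 and lower in 4 of 16. Adjusted over the list alone, the rod counts were 1 higher and 5 lower, the shared counts did not change, and after rescaling by the median of ratios 1 shared gene was higher and 4 were lower. Lrit1 was higher by 0.82 and Rgs9, which speeds the inactivation of transducin, fell by 0.80. Transcription factors were higher in 1 and lower in 3 of 7, the same adjusted over the list alone. Obox6 fell by 2.86, and the serine protease gene Htra1 and the hydrolase gene Hddc3 rose by 1.10 and 1.25. 91 genes were higher and 71 lower in CrxRip/+, against 41 and 84 after rescaling by the median of ratios, and leaving out 1 sample at a time gave 78 to 93 called genes in place of 162. The largest adjusted p of the called genes named was 0.00244 (limma). Camera called cone genes (adjusted p = 1.72e-09, adjusted p = 0.176 with an estimated correlation) and rod genes (adjusted p = 0.0215, adjusted p = 0.433 with an estimated correlation) lower, and also bipolar genes (adjusted p = 0.0185, adjusted p = 0.176 with an estimated correlation), of which 2 of 4 were lower, or 3 adjusted over the list alone.

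CrxRip/Rip differed from Crx-/- in more genes in the full fit, but not with only the 2 genotypes fitted (133 called, against 140 for CrxRip/+). Nrl (-0.94) and Nr2e3 (-0.89) were lower in CrxRip/Rip, as were Rxrg (-1.04), Sall3, a zinc finger factor of cones (-0.82), and Samd7, which was at 0.15 ± 0.07 against 34.1 ± 6.79 FPKM (-4.92). All 10 cone genes were lower (the same adjusted over the list alone), including Gnb3 (-2.57), Ccdc136 (-2.15) and Cnga3, the cone channel subunit (-1.88). Rod genes fell in 8 of 9 and shared genes in 13 of 16, with the same counts adjusted over each list alone. Sag changed by -2.56, Pde6b by -2.64, Prph2 by -1.89, Pdc by -1.52 and Aipl1, a chaperone of the phosphodiesterase, by -1.59. Ankrd33 was higher (0.66), as were Slitrk6 (1.36) and Acbd7 (1.36), while Obox6 fell by 2.98. Of the transcription factors 6 of 7 fell and 1 rose, also when adjusted over the list alone. The totals were 103 higher and 131 lower, with a largest adjusted p of 0.00378 among the genes named (limma). Without Crx-/- replicate 2 the number called was 136, and with only these genotypes in the fit 133, in place of 234. Camera gave adjusted p = 9.36e-09 for cone genes, 2.74e-05 for rod genes, 7.12e-06 for shared genes and 0.00655 for transcription factors. The same lists had adjusted p = 0.176, 0.18, 0.25 and 0.191 with an estimated correlation.

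The Nrl-/- comparison at P2 asks what the absence of the rod factor does while rods would be forming. Most rod genes were lower, while cone genes were higher or not called. Nr2e3 was at 0.05 ± 0.07 FPKM against 132 ± 16.6, so it fell by 6.98, and Nrl itself fell by 6.11. Rod genes fell in 7 of 9, over all genes and adjusted over the list alone, with Sag (-4.75), Pde6b (-4.02) and the rod transducin gamma gene Gngt1 (-3.21) among them. Of the shared photoreceptor genes 12 of 16 fell and 1 rose (the same adjusted over the list alone), including Pdc (2.85 ± 0.07 against 142 ± 18.5 FPKM, -5.21), Rom1 (-2.58), Prph2 (-1.80) and the axonemal protein gene Rp1 (-2.50). Cone genes rose in 6 of 10 and none fell, with the same count adjusted over the list alone. Pde6c rose by 1.43 (7.65 ± 0.78 against 2.2 ± 0.14 FPKM), Pde6h by 0.70, Cnga3 by 0.56 and Ccdc136 by 0.50. Transcription factors fell in 6 of 7 and 1 rose (the same adjusted over the list alone), namely Sall3, by 1.52 (5.35 ± 0.78 against 1.2 ± 0 FPKM), while Samd7 fell by 3.66. Of the bipolar cell genes Lhx4 rose by 1.27 and Pcp2, which modulates G protein signalling, by 1.38. Moxd1 rose by 2.23, Lmo2 by 1.81 and Gm129, a circadian repressor, by 1.75. Rpl21 was higher by 1.90, with the reservation on pseudogenes given above.

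Over all genes of P2, 107 genes rose and 366 fell in Nrl-/-, and the median change of all genes was -0.76. The largest adjusted p among the called genes named was 0.00497 (limma). Rescaling by the median of ratios brought the median of all genes to -0.04 and left 188 genes higher and 96 lower, whereas moving the samples to the authors' own fold change scaling brought it to -0.67. After rescaling by the median of ratios 4 transcription factors were higher and 3 lower, 4 shared genes higher and 7 lower, 2 rod genes higher and 7 lower, and 10 of 10 cone genes higher. The falls of Rxrg (-0.65) and Thrb (-0.48) turned into rises of 0.28 and 0.41 under that rescaling. It also raised the changes of Pde6c, Pde6h, Cnga3, Ccdc136, Sall3, Lhx4, Pcp2 and Trp53inp1 by more than 1.5 times, to 2.33 for Pde6c, and reduced those of Prph2, Rom1, Rp1 and Egr1 by as much, to -0.79 for Prph2, with all of them still called. Camera called the cone list higher (camera adjusted p = 3.22e-04, adjusted p = 0.23 with an estimated correlation), the rod list lower (camera adjusted p = 0.0495, adjusted p = 0.496 with an estimated correlation) and the bipolar list higher (camera adjusted p = 0.0301, adjusted p = 0.176 with an estimated correlation). The shared list and the transcription factors were not called (camera adjusted p = 0.201 and 0.288).

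Markers of other cell types and states were few in the P2 table, and some of them were called. Pou4f3, a ganglion cell factor, was at 0.75 ± 0.07 FPKM in Nrl-/- against 2.0 ± 0.28 in wild type and fell by 0.78, a call that ended after rescaling by the median of ratios, and it was not called in the other 3 mutants. Trp53inp1, a target of p53, rose in Nrl-/- by 0.79 (27.7 ± 2.33 against 15.6 ± 0.78 FPKM) and in Crx-/- by 0.45. Egr1, an immediate early transcription factor, changed by -1.29 in CrxRip/+, -1.45 in CrxRip/Rip, -0.42 in Crx-/- and -1.18 in Nrl-/- from 3.65 ± 0.35 FPKM. Cabp5, a calcium-binding protein of bipolar cells, changed by -1.63 in CrxRip/+, -1.86 in CrxRip/Rip and -0.95 in Crx-/-, from 3.35 ± 0.35 FPKM. Among the bipolar list as a whole 1, 1, 1 and 0 of 4 genes fell and 0, 0, 2 and 2 rose in CrxRip/+, CrxRip/Rip, Crx-/- and Nrl-/-, with the same counts adjusted over the list alone. The progenitor gene Fgf15 was at 40.0 ± 7.28 FPKM in wild type, 40.9 ± 4.1 in CrxRip/+, 40.5 ± 2.12 in CrxRip/Rip, 26.9 ± 5.52 in Crx-/- and 16.2 ± 0.99 in Nrl-/-, called changes of -0.56 and -1.24 in the last 2. The glial gene Gfap was at 7.5 ± 3.68 FPKM in wild type and called in none of the 4 mutants, while Socs3, which restrains cytokine signals, changed by -0.51 in CrxRip/+ and -0.55 in CrxRip/Rip. Pigment gene Tyrp1 was between 1.85 ± 0.21 FPKM in wild type and 3.85 ± 1.2 in CrxRip/Rip, a called rise of 0.75, and the transthyretin gene Ttr rose in Crx-/- by 0.81. The pericyte gene Rgs5 was between 1.2 ± 0.14 in wild type and 2.65 ± 0.92 in Crx-/-, and the haemoglobin gene Hbb-bs, whose copies are near-identical, between 1.2 ± 0.99 in wild type and 2.9 ± 2.83 in CrxRip/Rip. The largest adjusted p of the called changes given for these markers was 0.0462 (limma). The calls of Fgf15, Socs3, Tyrp1 and Ttr and those of Egr1 and Trp53inp1 in Crx-/- ended in 1 or more alternatives. No amacrine, horizontal, microglial, lens or sex-linked marker and no Müller glia marker of the fixed lists was in this table, so none of these was analysed at P2.

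At P21 the comparison of CrxRip/+ with wild type asks what becomes of the photoreceptors that carry a single dominant allele. Rod genes were lower, and cone genes changed in both directions. Nrl was at 0.65 ± 0.35 FPKM against 447 ± 27.2 (-8.10) and Nr2e3 at 1.35 ± 0.49 against 211 ± 17.6 (-6.51). Gnat1, the rod transducin alpha subunit, was at 2.85 ± 2.47 FPKM against 4363 ± 15.1, and all 15 rod genes fell, also when adjusted over the list alone, among them Cnga1 (-7.76) and the rod exchanger Slc24a1 (-6.54). Opn1sw changed by -6.23, the middle-wave opsin Opn1mw by -5.90 and cone arrestin (Arr3) by -3.70, whereas Gngt2 rose by 3.16 (461 ± 56.2 against 50.7 ± 2.69 FPKM) and Cngb3, a cone channel subunit, by 1.56. Of 14 cone genes 6 rose and 5 fell, the same adjusted over the list alone. Pde6h was not called at 93.7 ± 79.5 against 82.4 ± 5.59 FPKM, a change of -0.13 that was 0.86 without CrxRip/+ replicate 1 and -1.11 without replicate 2. Shared photoreceptor genes fell in 25 of 32, over all genes and adjusted over the list alone, including Guca1b (36 ± 4.1 against 538 ± 15.7 FPKM, -3.87), Rom1 (-2.80), the actin bundler Fscn2 (-4.11) and the guanylate cyclase Gucy2f (-4.98). Transcription factors rose in 3 and fell in 6 of 12 (the same adjusted over the list alone). Rxrg rose by 2.32, Otx2, which acts upstream of Crx, by 0.92 and Prdm1, which favours photoreceptor over bipolar fate, by 1.06, while the rod factors Samd7 (-3.94), Esrrb (-5.09), Mef2c (-3.08) and Rorb (-1.16) were lower.

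Outside the lists Fabp7, a fatty acid binding protein of glia and progenitors, rose by 4.16 (47.7 ± 12 against 1.7 ± 0.42 FPKM), the kinesin gene Kif19a by 3.69, the cholecystokinin receptor gene Cckbr by 3.35 and Myocd, a smooth muscle coactivator, by 3.35. Genes of the retinal pigment epithelium (RPE), which lies outside the neural retina, were higher in the same libraries, in 5 of 8 with a median change of 0.88. In all 591 genes rose and 524 fell of 1497, and the largest adjusted p among the called genes named was 1.23e-04 (limma). The balance turned to 509 higher and 599 lower after rescaling by the median of ratios, and to 484 and 606 at the authors' fold change scaling. Moving the samples to that scaling altered the change of single genes by a median of -0.19 in CrxRip/+, -0.18 in CrxRip/Rip, -0.2 in Crx-/- and -0.09 in Nrl-/-, so P21 changes smaller than these depend on the scaling. By camera rod genes (camera adjusted p = 5.04e-08, adjusted p = 0.298 with an estimated correlation) and shared genes (camera adjusted p = 6.32e-07, adjusted p = 0.298 with an estimated correlation) were lower than the rest of the table, while the cone list, with members on both sides, was not called (adjusted p = 0.914), nor were the transcription factors (0.277).

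**Figure D2:**
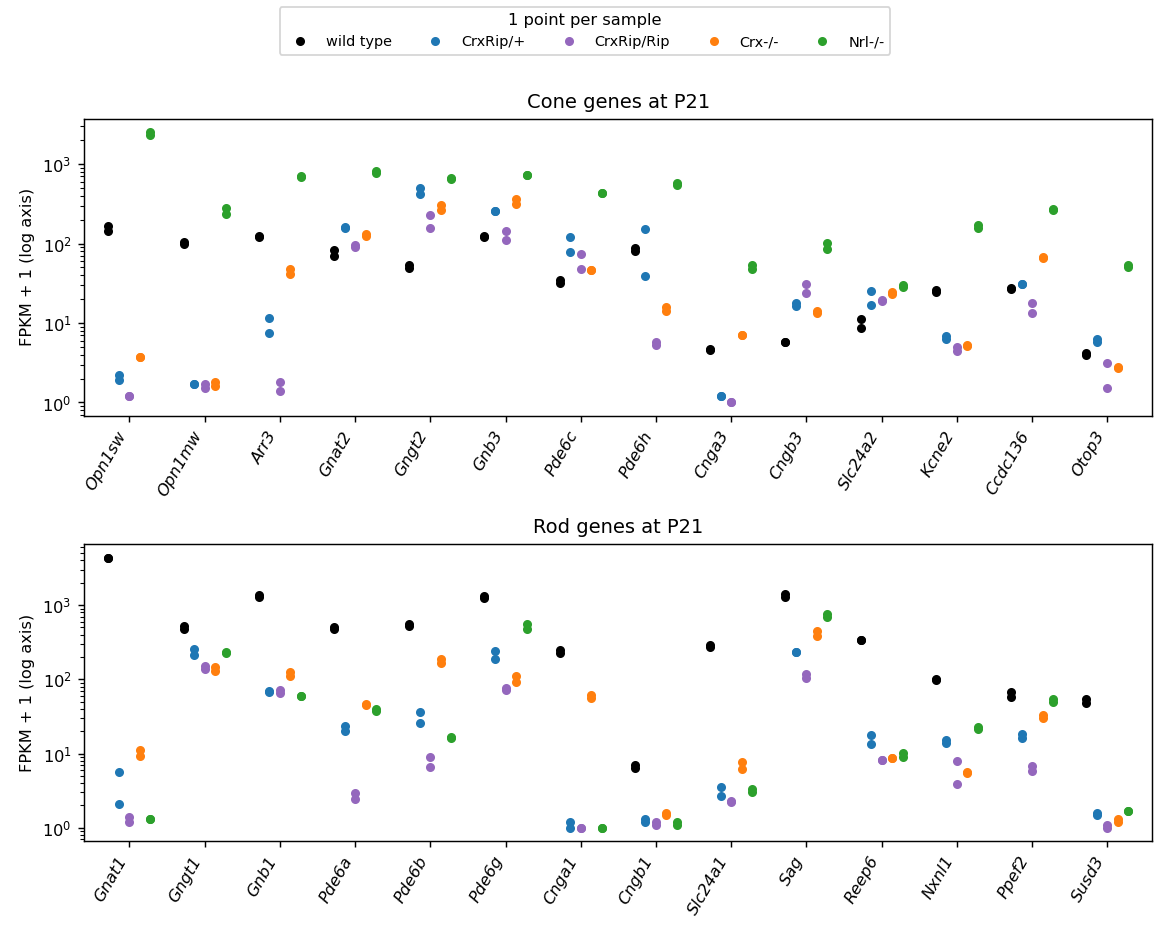
FPKM (log axis of FPKM + 1) of cone and rod genes of the fixed lists at P21, with 1 point per sample and 1 colour per genotype, 2 samples per genotype. Cone genes lay above the wild-type samples in Nrl-/- in 14 of 14 cases, and rod genes lay below them in every mutant, where Ppef2 in Nrl-/- was the 1 rod gene not called.

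In CrxRip/Rip at P21 several rod genes were at or near 0. Nr2e3 was listed at 0 and Nrl was at 0.15 ± 0.07 FPKM, against 211 ± 17.6 and 447 ± 27.2 in wild type. All 15 rod genes and 30 of 32 shared genes fell, the same adjusted over each list alone. Gnat1 was at 0.3 ± 0.14 FPKM (-11.72), Pde6a, the alpha subunit of the rod phosphodiesterase, at 1.65 ± 0.35 (-7.53), and Cnga1 was listed at 0. Guca1b changed by -5.58, the matrix proteoglycan Impg1 by -5.15, Fscn2 by -5.11 and Rcvrn by -6.16. Cone genes rose in 5 and fell in 8 of 14, also when adjusted over the list alone. Among the rises, Gnat2 was at 0.06 and not called at the authors' fold change scaling, and Pde6c was at 0.51 without CrxRip/Rip replicate 1. Opn1sw changed by -7.0, Opn1mw by -5.99, Arr3 by -6.25 and Pde6h by -3.92, while Gngt2 rose by 1.88 and Cngb3 by 2.22. Otx2 rose by 1.76 (276 ± 18 against 80.6 ± 0.64 FPKM), Prdm1 by 1.44 and Rxrg by 1.22, and Samd7, Esrrb, Mef2c and Rorb changed by -5.38, -6.06, -2.94 and -0.77. In total 4 of 12 transcription factors were higher and 7 lower, the same adjusted over the list alone.

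Fabp7 was at 203 ± 77 FPKM against 1.7 ± 0.42 (6.20), and Chrnb4, a nicotinic receptor subunit, at 41.9 ± 9.26 against 0.8 ± 0.14 (4.56). The transporter ATPase gene Atp13a5 rose by 3.74 and Kif19a by 4.30. RPE genes were higher in 7 of 8, with a median change of 1.26. In all 544 genes rose and 663 fell, with a largest adjusted p of 0.00103 among those named (limma). Camera called rod genes (camera adjusted p = 6.32e-07, adjusted p = 0.339 with an estimated correlation) and shared genes (camera adjusted p = 1.48e-07, adjusted p = 0.298 with an estimated correlation) and neither cone genes (adjusted p = 0.579) nor transcription factors (0.5).

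Set directly against CrxRip/+ at P21, the CrxRip/Rip retina was lower in most photoreceptor groups. Shared genes fell in 26 of 32, cone genes in 11 of 14 with 1 higher, and rod genes in 11 of 15, the same adjusted over each list alone. Rcvrn changed by -3.61 (6.9 ± 4.1 against 95.7 ± 50.1 FPKM), Rdh8, a retinol dehydrogenase of the outer segment, by -3.18, Cabp4, a calcium-binding protein of the photoreceptor synapse, by -2.44 and Impg1 by -3.63. Pde6a changed by -3.05, Pde6b by -1.99, Pde6g by -1.53, Arr3 by -2.55 and Gngt2 by -1.27 (193 ± 50.8 against 461 ± 56.2 FPKM). Otx2 was higher by 0.85, and Samd7 (-1.44) and Rxrg (-1.10) were lower. Transcription factors were higher in 2 (4 adjusted over the list alone) and lower in 7 (7) of 12. Chrnb4 rose by 2.97 and Arid3c, a gene of the ARID family of DNA-binding proteins, by 3.45. The RPE list had 1 member higher and 0 lower of 8, and 0 higher adjusted over the list alone. The totals were 165 higher and 538 lower with a median change of -0.22, against 304 and 269 after rescaling by the median of ratios, and 279 called in place of 703 with only these genotypes in the fit. For the called genes named the largest adjusted p was 8.88e-04 (limma). Camera called shared genes (camera adjusted p = 1.81e-05, adjusted p = 0.298 with an estimated correlation) and rod genes (camera adjusted p = 0.00877, adjusted p = 0.764 with an estimated correlation) and not cone genes (adjusted p = 0.0713).

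Crx-/- at P21 retained part of the rod regulators while rod genes and most shared genes were lower. Nrl was at 84.6 ± 3.68 FPKM against 447 ± 27.2 (-2.39), and Samd7 was above wild type at 139 ± 9.62 against 42.6 ± 1.34 (1.69). Ankrd33 changed by -4.44 (2.5 ± 0.42 against 74.7 ± 4.95 FPKM), Esrrb by -3.64 and Mef2c by -3.14, whereas Rxrg rose by 3.22, Prdm1 by 1.67 and Otx2 by 1.29. Transcription factors were higher in 4 and lower in 6 of 12, also when adjusted over the list alone. All 15 rod genes and 29 of 32 shared genes fell, the same adjusted over each list alone. Gnat1 was at 9.2 ± 1.13 FPKM (-8.75), Slc24a1 at 5.85 ± 1.06 (-5.39) and Susd3, a sushi domain gene of rods, at 0.25 ± 0.07 (-5.37). Guca1b changed by -5.62, Rcvrn by -6.0, Gucy2f by -4.59 and Fscn2 by -5.10, while Rbp3, the retinoid carrier between photoreceptors and RPE, was at 760.2 ± 65.5 against 758 ± 30.2 FPKM and was not called. Cone genes rose in 7 and fell in 5 of 14, the same adjusted over the list alone. Opn1mw changed by -5.90, Opn1sw by -5.37 and Pde6h by -2.47, and Gngt2 rose by 2.46, Gnb3 by 1.47 and Ccdc136 by 1.27.

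Among the largest rises were Fabp7 (156 ± 9.48 against 1.7 ± 0.42 FPKM, 5.87), the retinol carrier gene Rbp4 (5.23), the connexin gene Gje1 (4.56) and Obox6 (4.15). The keratin gene Krt73 was at 14.1 ± 2.12 FPKM and listed at 0 in wild type. All 8 RPE genes were higher, with a median change of 1.46. 596 genes rose and 621 fell in all, with a largest adjusted p of 0.00182 for the called genes named (limma). By camera rod genes (camera adjusted p = 2.87e-06, adjusted p = 0.37 with an estimated correlation) and shared genes (camera adjusted p = 3.06e-07, adjusted p = 0.298 with an estimated correlation) were lower, and cone genes (adjusted p = 0.889) and transcription factors (0.742) were not called.

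The CrxRip genotypes and Crx-/- were also compared directly at P21. Nrl was at 0.65 ± 0.35 FPKM in CrxRip/+ against 84.6 ± 3.68 in Crx-/- (-5.71), Nr2e3 at 1.35 ± 0.49 against 114 ± 5.66 (-5.63) and Samd7 at 1.85 ± 0.21 against 139 ± 9.62 (-5.62), while Ankrd33 was higher by 4.80 and Crx by 0.78. Of the transcription factors 2 were higher and 8 lower of 12. Rod genes were higher in 5 and lower in 10 of 15, with Cnga1 at -5.72 and Pde6b at -2.53. Shared genes were higher in 19 (20 adjusted over the list alone) and lower in 6 of 32, with Rcvrn (3.45), Rdh8 (2.46) and Guca1b (1.75) on the higher side. Cone genes were higher in 6 and lower in 5 of 14, with Cnga3 (-2.54) and Arr3 (-2.26) lower. Counts of the rod, cone and transcription factor lists were the same adjusted over each list alone. Tmem26, a membrane protein gene, was higher by 3.02. The RPE list had 1 member lower of 8, and 0 adjusted over the list alone. 448 genes were higher and 340 lower in CrxRip/+, against 386 and 413 after rescaling by the median of ratios, and the largest adjusted p of the called genes named was 0.00114 (limma). Camera called the transcription factors lower (camera adjusted p = 0.028, adjusted p = 0.371 with an estimated correlation) and not the rod list (adjusted p = 0.0713), the shared list (0.0627) or the cone list (0.76).

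In CrxRip/Rip the same factors were lower than in Crx-/-, with Samd7 at 0.05 ± 0.07 against 139 ± 9.62 FPKM (-7.06), Nrl at -6.22, Esrrb at -2.43 and Rxrg at -2.0, and Ankrd33 was higher (4.17). Nr2e3 was listed at 0 in CrxRip/Rip. Rod genes fell in 11 of 15, including Pde6b (-4.52) and Pde6a (-4.12), and cone genes in 8 of 14 with 1 higher, both the same adjusted over the list alone. Arr3 changed by -4.81, Ccdc136 by -2.09 and Opn1sw by -1.62. Shared genes were higher in 5 and lower in 17 of 32 (6 and 19 adjusted over the list alone), with Impg1 (-4.37), Aipl1 (-2.30) and Pdc (196 ± 33.9 against 715 ± 69.6 FPKM, -1.87) lower. Transcription factors were higher in 3 and lower in 6 of 12, the same adjusted over the list alone. Acbd7 was at 27.2 ± 2.26 against 1.0 ± 0.14 FPKM (3.82) and Atp13a5 rose by 3.79. No RPE gene was called in this comparison. The totals were 291 higher and 508 lower in CrxRip/Rip, and 406 and 391 after rescaling by the median of ratios. Named genes had a largest adjusted p of 3.20e-05 (limma). Camera called rod genes (camera adjusted p = 6.52e-04, adjusted p = 0.604 with an estimated correlation) and not cone genes (adjusted p = 0.0891), shared genes (0.281) or transcription factors (0.507).

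In Nrl-/- at P21 cone genes were higher and most rod genes lower. All 14 cone genes rose, the same adjusted over the list alone. Opn1sw was at 2399.8 ± 143 FPKM against 153 ± 16.6 (3.97), Pde6c at 427 ± 2.26 against 32.1 ± 1.7 (3.70), Cngb3 at 91.6 ± 11.7 against 4.75 ± 0.07 (4.0) and Otop3 at 51.7 ± 1.91 against 3.1 ± 0.14 (3.68). Rod genes fell in 14 of 15, also when adjusted over the list alone. Gnat1 was at 0.3 ± 0 FPKM (-11.71) and Slc24a1 at 2.15 ± 0.21 (-6.50), and Cnga1 was listed at 0. Among shared genes 23 of 32 fell and 3 rose (the same adjusted over the list alone), with Gucy2f at -4.71, Fscn2 at -3.66, Guca1b at -3.42 and Rom1 at -2.15. Nr2e3 was at 0.1 ± 0.14 FPKM (-7.60), and Esrrb, Mef2c, Rorb and Samd7 changed by -4.82, -3.01, -1.16 and -1.08. Rxrg rose by 2.47, Sall3 by 1.98, Prdm1 by 1.75 and Otx2 by 0.53 (0.3 after rescaling by the median of ratios). Transcription factors were higher in 5 and lower in 6 of 12, the same adjusted over the list alone. Fabp7 rose by 4.72 here as well (70.3 ± 9.4 against 1.7 ± 0.42 FPKM). Of the RPE genes 7 of 8 were higher, with a median change of 1.06, and 5 were called after rescaling by the median of ratios. 605 genes rose and 476 fell, with a largest adjusted p of 0.00224 among those named (limma). After rescaling by the median of ratios 510 were higher and 556 lower. Camera called cone genes higher (camera adjusted p = 3.74e-06, adjusted p = 0.298 with an estimated correlation) and rod genes (camera adjusted p = 5.04e-08, adjusted p = 0.298 with an estimated correlation) and shared genes (camera adjusted p = 6.88e-05, adjusted p = 0.298 with an estimated correlation) lower. Changes against wild type that were called in 1 mutant and not in another were compared only through the direct contrasts given above, and Nrl-/- was not tested against the other mutants.

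Some genes of glial reaction, immune cells and cell death were called higher in several mutants at P21. Gfap, the intermediate filament of reactive Müller glia and astrocytes, rose by 1.93 in CrxRip/+ (18.6 ± 3.89 against 4.1 ± 0.57 FPKM), 0.74 in CrxRip/Rip, 2.39 in Crx-/- and 1.0 in Nrl-/-, and Stat3, which drives the glial response, by 1.35, 1.04, 1.10 and 1.0. Of the 9 gliosis genes 6, 2, 7 and 4 rose in these mutants and none fell, the same adjusted over the list alone. Set against CrxRip/+, Gfap changed by -1.19 in CrxRip/Rip, and set against Crx-/- by -1.65. C4b and Serpina3n, members of gene families with close paralogs and therefore less certain, rose in Crx-/- by 1.79 and 2.16. Ctss, a lysosomal protease of microglia, rose by 0.96 in CrxRip/+ and 1.09 in Crx-/-, where all 3 microglial genes in the table were called, over the table and adjusted over the list alone, but 1 in each at the authors' fold change scaling. The microglial list had 0 called genes in CrxRip/Rip and 1 in Nrl-/- (0 adjusted over the list alone). Cdkn1a, the cell cycle inhibitor p21, rose by 1.26 in CrxRip/+, 1.54 in CrxRip/Rip and 2.64 in Crx-/-. Of 4 cell death genes 3, 2, 3 and 2 rose and 1, 1, 1 and 0 fell in CrxRip/+, CrxRip/Rip, Crx-/- and Nrl-/-, the same adjusted over the list alone. Egr1 rose in all 4 mutants, by 3.65, 3.42, 3.59 and 3.11, and immediate early genes as a list had 5, 4, 4 and 4 of 5 higher and 0, 0, 0 and 1 lower, the same adjusted over the list alone. None of these lists was called by camera at P21 (limma), where the lowest adjusted p was 0.0713, for immediate early genes in CrxRip/+.

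Most of the 8 RPE genes in the table were called higher in each mutant at P21. Rpe65, the retinoid isomerase, rose by 1.32 in CrxRip/+ (3.5 ± 1.13 against 0.8 ± 0.42 FPKM), 1.55 in CrxRip/Rip, 1.53 in Crx-/- and 1.34 in Nrl-/-, and Rgr, an RPE and Müller glia opsin, by 1.74, 1.85, 1.76 and 1.53. Without wild-type replicate 1 the Rgr change in Nrl-/- was 0.96. The counts of 5, 7, 8 and 7 of 8 were the same adjusted over the list alone, and camera did not call the list (lowest adjusted p = 0.0846, in CrxRip/Rip). Kdr, a vascular growth factor receptor that horizontal cells also express, rose by 1.27, 1.28 and 1.11 in CrxRip/+, CrxRip/Rip and Crx-/-. It was the one vascular gene of 5 that rose there, 1 rose in Nrl-/-, and 0, 3, 2 and 0 fell in the 4 mutants, among them the tight junction gene Cldn5 in CrxRip/Rip (-0.65), the same adjusted over the list alone. Erythrocyte genes were called in Nrl-/- alone, 2 of 5 (0 adjusted over the list alone and 0 after rescaling by the median of ratios), and both are near-identical haemoglobin genes. Lens crystallin genes were called in none, and Cryaa was at 13.3 ± 11.2 FPKM in wild type, an SD near its mean. Among progenitor and cell cycle genes Dll1, the Notch ligand, rose by 1.34 in CrxRip/+, 0.78 in CrxRip/Rip and 1.06 in Nrl-/-, and cyclin A2 (Ccna2) changed by -0.69, -1.07 and -1.21. That list had 3, 3, 3 and 2 of 5 higher and 1, 1, 0 and 1 lower, the same adjusted over the list alone, and in Crx-/- it had 1 higher and 1 lower at the authors' fold change scaling.

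Markers of inner retinal neurons moved in both directions. Cabp5 rose in Nrl-/- by 2.0 (157 ± 2.9 against 39.1 ± 9.26 FPKM) and fell in CrxRip/Rip (-0.83), and Lhx4 rose in Nrl-/- by 1.90, in CrxRip/Rip by 0.92 and in Crx-/- by 0.69. Bipolar genes were higher in 1, 1, 2 and 2 and lower in 1, 3, 1 and 1 of 4 in CrxRip/+, CrxRip/Rip, Crx-/- and Nrl-/-. Adjusted over the list alone the CrxRip/+ count was 0 higher, the others did not change, and in Crx-/- 1 was higher and 2 were lower at the authors' fold change scaling. Prkca, the protein kinase of rod bipolar cells, changed by -0.44 in CrxRip/+, -0.90 in CrxRip/Rip and -0.35 in Nrl-/-. Sphkap, a kinase A anchoring protein of horizontal cells, rose by 0.63 in CrxRip/Rip (0.41 at the authors' fold change scaling), 0.84 in Crx-/- and 1.97 in Nrl-/-, while Calb1, the calbindin of horizontal cells, fell in CrxRip/Rip (-0.64) and Crx-/- (-0.47). Horizontal cell genes were higher in 0, 1, 1 and 1 and lower in 0, 2, 1 and 0 of 3, the same adjusted over the list alone. Sox9, the Müller glia factor, rose by 0.48 in CrxRip/+, 1.27 in CrxRip/Rip and 0.45 in Crx-/-. The amacrine peptide gene Sst, at 3.3 ± 0.42 FPKM in wild type, changed by -0.67 in Crx-/- and -0.52 in Nrl-/- and was not called in the CrxRip genotypes. The calls of Sst, of Sox9 in CrxRip/+ and Crx-/- and of Prkca in CrxRip/+ and Nrl-/- ended in 1 or more alternatives. Ganglion cell and sex-linked genes of the fixed lists were not analysed at P21.

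**Figure D3:**
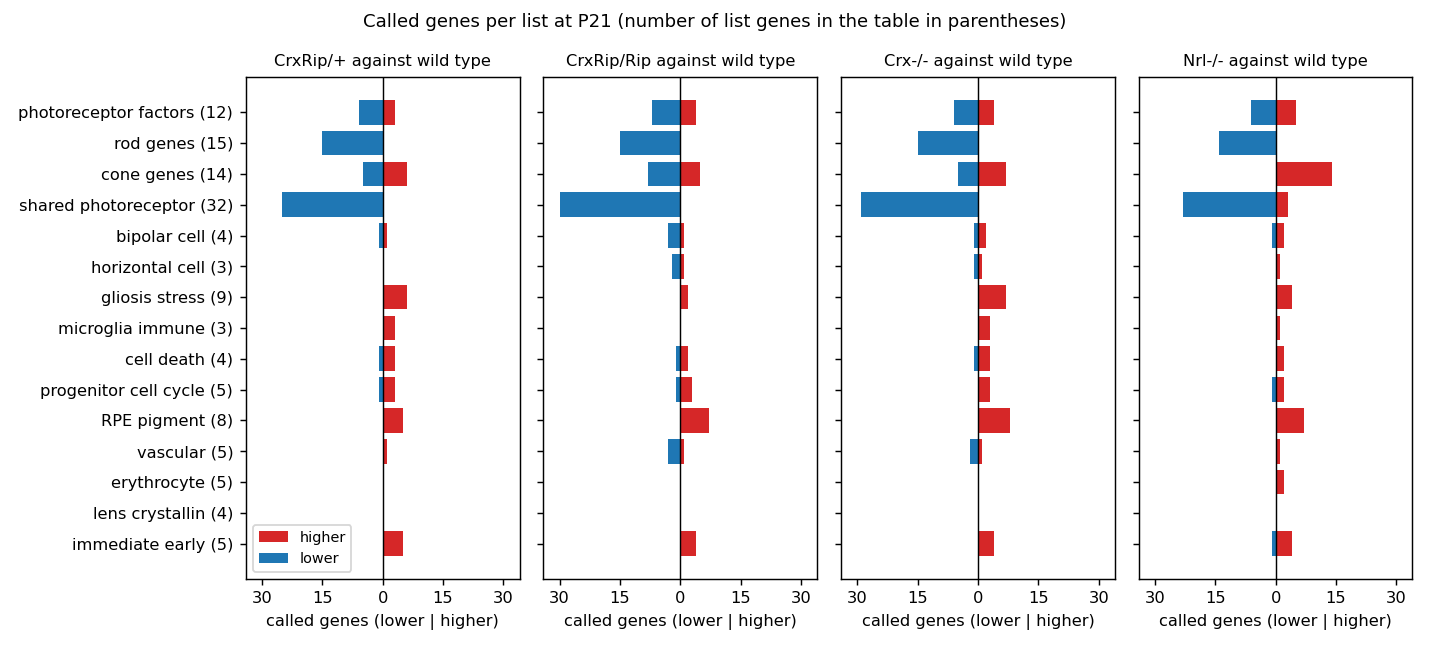
Number of called genes per fixed list at P21 (adjusted p under 0.05, limma) in each of 4 mutants against wild type, with higher genes as bars to the right of 0 and lower genes as bars to the left. The rod list had 15 lower genes in CrxRip/+ and the cone list 14 higher genes in Nrl-/-.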

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

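The tests of transcript GC content, transcript length and scaling, of the other cell markers, and of chromosome position and partial copies were chosen only after the results they bear on were seen. Random lists for the RPE genes and the first search for whole copies were set out before.

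Some genes moved in opposite directions at the 2 ages against wild type. Among the 198 genes in both tables, only members of the fixed lists were examined for this. In 1 or more mutants 11 members were called lower at P2 and higher at P21, with no overlap between mutant and wild-type samples. They made 21 combinations of gene and mutant. What singled them out is this difference between ages, which was not tested, and the tables of the ages were scaled separately. Values given are the P21 change minus the P2 change on the log2 scale. Egr1, an immediate early gene, differed in all 4 mutants, by 4.93 in CrxRip/+, 4.87 in CrxRip/Rip, 4.0 in Crx-/- and 4.29 in Nrl-/-. The cone genes Gnat2, Pde6c and Cngb3 differed by 3.3, 2.64 and 2.61 in CrxRip/+ and by 2.76, 2.14 and 3.9 in CrxRip/Rip. Gnb3 differed by 2.47 in CrxRip/+, Gngt2 by 3.54 in CrxRip/Rip and Gnat2 by 1.33 in Crx-/-. The cone receptor gene Rxrg differed by 3.15 in CrxRip/+, 2.54 in CrxRip/Rip and 3.12 in Nrl-/-, and the zinc finger gene Sall3 by 1.13 in CrxRip/Rip. The bipolar gene Cabp5 differed by 2.05 in CrxRip/+ and 1.46 in Crx-/-. In Nrl-/- the regulator Ankrd33 differed by 0.69 and Jun by 1.87. No biological explanation for the opposite directions was tested.

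Both calls held under every alternative run on single genes for 11 of these 21 combinations, and 10 lost or reversed a call in at least 1. The 2-fold minimum was run on counts alone, and the filter on mean FPKM left genes under 5 FPKM unchecked. Those that held were Egr1 in CrxRip/+, CrxRip/Rip and Nrl-/-, Rxrg in both CrxRip genotypes, Cngb3, Pde6c, Gnat2 and Gnb3 in CrxRip/+, and Cngb3 and Gngt2 in CrxRip/Rip. After rescaling by the median of ratios the P2 changes in Nrl-/- were 0.28 for Rxrg and 0.58 for Ankrd33, both reversed, and -0.48 for Jun, which was not called. At the scaling of the authors' fold changes the P21 changes of Cabp5 in CrxRip/+ (0.2) and Crx-/- (0.28), of Gnat2 (0.06) and Sall3 (0.49) in CrxRip/Rip and of Ankrd33 (0.31) and Jun (0.36) in Nrl-/- were not called.

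Single samples ended calls too. For Cabp5 at P21 these were wild-type replicate 1 (0.18 without it in CrxRip/+ and 0.27 in Crx-/-), CrxRip/+ replicate 1 (0.28) and Crx-/- replicates 1 (0.44) and 2 (0.57). For Sall3 in CrxRip/Rip they were either wild-type replicate (-0.51 at P2, 0.62 at P21) and CrxRip/Rip replicate 2 (-0.46 and 0.21). Pde6c in CrxRip/Rip at P21 was at 0.78 without wild-type replicate 1 and 0.51 without CrxRip/Rip replicate 1. Gnat2 in CrxRip/Rip at P21 was at 0.14 without wild-type replicate 2, 0.32 without CrxRip/Rip replicate 1 and 0.23 without replicate 2. In Crx-/- at P2 Gnat2 was at -0.50 without wild-type replicate 2 and -0.54 without Crx-/- replicate 1, and Egr1 at -0.49 and -0.34 without wild-type replicates 1 and 2 and at -0.25 without Crx-/- replicate 2. In Nrl-/- Ankrd33 was at -0.25 and -0.24 at P2 without wild-type replicate 1 and Nrl-/- replicate 1, and at P21 leaving out any 1 of the 4 samples ended the call (0.35 to 0.49). Jun in Nrl-/- at P21 was at 0.44 and 0.47 without wild-type replicates 1 and 2 and at 0.34 without Nrl-/- replicate 1. With the replicate number as a block the P21 calls of Cabp5 in CrxRip/+ (limma, adjusted p = 0.065) and Ankrd33 in Nrl-/- (adjusted p = 0.0576) ended, and the other settings ended calls only in combinations named here.

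The first pattern weighed is the fall of the P2 table in Nrl-/-, where 366 of 473 called genes were lower and the median change was -0.76. Of the genes in this table, 342 had passed the authors' adjusted p and 2-fold threshold in Nrl-/- against wild type, 264 of them lower. The count and the median thus follow in part from how genes were selected, and they do not measure a fall of the whole transcriptome. The change was nearly unrelated to transcript GC content (Spearman correlation across genes -0.04, genes not being independent replicates) and to transcript length (-0.11). Among these selected genes, that argues against a bias graded by GC content or length. A rank correlation cannot see a fall common to all genes, and no reads were analysed here, so RNA degradation stays open. At the scaling of the authors' fold changes the median was still -0.67. That scaling moves the ratio of Nrl-/- to wild type by 0.17 on the log2 scale, too little to bring the median near 0. It shows only that a difference of that size does not account for the fall. The median of ratios brings the median change to -0.04, but that step sets the typical gene of a preselected table to no change, so it decides nothing, and a larger difference in RNA composition stays open. An effect of the missing Nrl gene on many transcripts at P2 may also explain it and was not tested. The ribosomal protein gene Rplp0, at 274 ± 29.4 FPKM in wild type and 284 ± 49.4 in Nrl-/-, was not called. It is 1 of 93 genes not called in this comparison and cannot tell these explanations apart.

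The second pattern is the higher RPE and pigment genes of all 4 mutants at P21, whose medians over 8 genes were 0.88, 1.26, 1.46 and 1.06 in CrxRip/+, CrxRip/Rip, Crx-/- and Nrl-/-. At the scaling of the authors' fold changes the lowest of these medians was 0.71. That scaling moves the ratios of the mutants to wild type by -0.11 to -0.23 on the log2 scale, too little to remove the rise. It shows only that a common difference of that size does not account for the rise, and a larger one was not tested. A lower share of rods would raise the markers of other cell types alike. The medians of 14 such markers were -0.06, -0.48, -0.24 and 0.22, at least 0.84 below the RPE list, so these markers showed no equal rise. They were in the table only because they had passed the authors' threshold in some comparison. Markers outside the table may have moved otherwise, so the explanation is not excluded. With the 3 microglial genes added the medians were -0.04, -0.36, 0 and 0.25, although these 3 alone were at 0.82, -0.09, 0.83 and 0.49 and the gliosis list at 1.17, 0.15, 1.13 and 0.80. The 8 genes rose and fell together between the 2 samples of a genotype. Their mean pairwise correlation, taken without centring, was 0.71, against a median of 0.01 for random lists matched on mean expression (percentile 100). RPE cells carried over with the retina in varying amounts would give this. Any list of genes expressed together may give it too, and the random lists were not of that kind. Carry-over thus stays open. A change within the RPE or in its adhesion to a retina with altered photoreceptors is the biological alternative that the genotypes give, and it was not tested.

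The third pattern is the set of 6 genes higher in all 4 mutants at P2, Hmgb1, Rpl21, Polr1d, Lmo2, Moxd1 and Spsb1. All 4 comparisons share the same 2 wild-type samples, so they are not independent, and the number of such genes expected without a change was not computed. Hmgb1, Rpl21 and Polr1d lie within 3 Mb on chromosome 5, which random lists from the table matched with a permutation p = 0.0008, so a difference of 1 chromosome region between the wild-type and the mutant animals may lie behind these 3. The same genes, 3 of 3, contain most of the sequence of at least 1 pseudogene each (Hmgb1 21, Rpl21 19 and Polr1d 1), so reads shared with copies stay open as well, and the explanations cannot be ranked from these values. The planned search for pseudogenes holding at least 50 percent of a whole transcript found 0, but it decided nothing, because the copies of these genes are too short to reach that share. For Lmo2, Moxd1 and Spsb1, 0 of 3 matched a pseudogene, which argues against shared reads there, and an effect common to the 4 genotypes was not tested.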

How the results depend on the processing

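The scaling to the authors' fold changes was added only after the results were seen, and the other alternatives were planned. A count is called similar here when it stayed within 1.5 times the reported one.

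Of 361 changes given for single genes, 332 kept their direction and their side of the threshold under every alternative run on them, a share raised by selection, since rule genes whose call changed were mostly not named. The 2-fold minimum was run on counts alone and the filter on mean FPKM on 271 of these changes. 4 reversed and the other 25 lost their call in 1 or more. After rescaling by the median of ratios Ankrd33 was at 0.58, Rxrg at 0.28 and Thrb at 0.41 in Nrl-/- at P2, because that step raises every gene of these samples. Pde6h in CrxRip/+ at P21 was at 0.86 without CrxRip/+ replicate 1 and at -1.11 without CrxRip/+ replicate 2, since the 2 samples lay on either side of wild type. Pou4f3 in Nrl-/- at P2 kept its direction and lost its call under the median of ratios, as did Fgf15 there (-0.22). Markers that kept their direction and lost their call on leaving out 1 sample were Socs3 in both CrxRip genotypes, Tyrp1 in CrxRip/Rip, and Fgf15, Trp53inp1 and Ttr in Crx-/- at P2. Without CrxRip/Rip replicate 2 the changes of Socs3 and Tyrp1 there were -0.35 and 0.49, still called, and Fgf15 in Crx-/- was at -0.37 without wild-type replicate 1 and -0.35 without Crx-/- replicate 2. At P21 they were Sst in Crx-/- and Nrl-/-, Prkca in CrxRip/+ and Nrl-/-, and Sox9 in CrxRip/+ (0.3 without CrxRip/+ replicate 2) and Crx-/-. At the authors' scaling Fgf15 in Crx-/- (-0.54) and Sox9 in CrxRip/+ (0.31) and Crx-/- (0.28) were not called either. The others that lost a call belong to the genes with opposite changes at the 2 ages, given above with the samples concerned. Called changes moved by more than 1.5 times in 39 cases with a pseudocount of 0.1, 162 with 5, 27 with the median of ratios, 7 with the authors' scaling and 15 on leaving out a sample, and beyond the pseudocount and the scaling the cause was not tested.

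The numbers of called genes were similar in all 14 comparisons with a pseudocount of 0.1 or 5, array weights, the replicate block and the authors' scaling. Replicate numbers showed no consistent pairing, and the replicate block gave similar counts, although it ended 2 calls given above. Rescaling by the median of ratios lowered the P2 Nrl-/- count to 284 and was similar in the other 13, although it moved the balance of higher and lower genes in some of them. Restricting the tables to genes with a mean of at least 5 FPKM leaves fewer genes to test. The P2 counts became 42 in CrxRip/+, 71 in CrxRip/Rip, 56 in Crx-/- and 190 in Nrl-/-, and 52 for CrxRip/+ against Crx-/-, 98 for CrxRip/Rip against Crx-/- and 45 for CrxRip/Rip against CrxRip/+. At P21 they became 720, 770, 778 and 687 in the mutants against wild type and 529 for CrxRip/Rip against Crx-/-, and the other 2 were similar.

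Asking for a 2-fold change as well lowers every count by construction. At P2 it left 27, 76, 33 and 185 genes in CrxRip/+, CrxRip/Rip, Crx-/- and Nrl-/- against wild type, 22 and 65 in CrxRip/+ and CrxRip/Rip against Crx-/-, and 25 in CrxRip/Rip against CrxRip/+. At P21 it left 449, 611, 611 and 461 against wild type, and 211, 242 and 165 in the same comparisons of mutants. Fitting only the 2 genotypes compared leaves fewer samples for the spread and takes it from those genotypes alone. It gave 133 genes for CrxRip/Rip against Crx-/- and 43 for CrxRip/Rip against CrxRip/+ at P2, and 279 for the latter at P21, and was similar in 11 comparisons. Spread was unequal between genotypes. At P21 the SD over genes of the log2 difference between the 2 samples was 0.40 in CrxRip/+ and 0.46 in CrxRip/Rip, against 0.17 to 0.23 in the others. At P2 it was 0.52 in CrxRip/Rip, 0.40 in wild type, 0.34 in CrxRip/+, 0.23 in Crx-/- and 0.20 in Nrl-/-. The shared spread of the main fit may thus be too small for comparisons of CrxRip genotypes. At P2 it may also be too small for the wild-type samples, with which every mutant was compared.

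Leaving out 1 sample at a time leaves a group of 1, whose lone sample is assumed to vary like the other groups. Of these 56 fits 45 were similar and 11 called fewer genes, all at P2. The counts ran from 55 (without wild-type replicate 2) to 74 in CrxRip/+, 72 (without Crx-/- replicate 2) to 92 in Crx-/-, 78 to 93 for CrxRip/+ against Crx-/-, 136 (without Crx-/- replicate 2) to 235 for CrxRip/Rip against Crx-/- and 51 (without CrxRip/+ replicate 2) to 75 for CrxRip/Rip against CrxRip/+. Ranges of the other comparisons at P2 were 131 to 187 in CrxRip/Rip and 444 to 458 in Nrl-/-. At P21 they were 946 to 1057, 1110 to 1196, 1111 to 1128 and 919 to 966 against wild type, and 592 to 731, 573 to 785 and 590 to 664 between mutants. Not every fit with fewer samples called fewer genes, since 187 in CrxRip/Rip at P2 lay above the reported 153. Why the P2 comparisons of CrxRip/+ and wild type with Crx-/- lost most was not tested.

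Camera called 23 of 35 list tests at P2 and 13 of 105 at P21, and the same numbers with the replicate block. With an estimated correlation camera called 0 and 0. At P2 the estimates ran from 0.19 for transcription factors to 0.56 for shared genes, and correlated genes of a list count as less evidence. The bipolar list had an estimate of -0.11, yet its camera p in Nrl-/- rose from 0.0189 to 0.0625. Correlation within lists is thus not the whole reason. With an estimated correlation camera takes its p from the 5 residual degrees of freedom, and with the preset one from the number of genes. The p values rise for that reason as well, so the lack of calls reflects low power too. How much each of the 2 reasons contributes was not separated. Fry, which does not compare a list with other genes, called 32 and 62. Read depth is unknown, so what it limits could not be measured. Values near the printed step of 0.1 FPKM carry the least information.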

Other observations

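These observations were chosen after the values were seen, and they are reported as values.

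Obox6, a homeobox gene of the early embryo, was high in Crx-/- at both ages. It was at 8.1 ± 0.42 FPKM at P2 and 22 ± 1.41 at P21, against 0.3 ± 0 and 0.3 ± 0.14 in wild type, and it was not called in the CrxRip genotypes at either age. In Nrl-/- it was called at P21 alone, at 0.65 ± 0.21 FPKM. Obox6 (NM_145710, chromosome 7, 15833250 to 15839679) lies 26.3 kilobases from Crx in GRCm38, with 0 protein-coding genes between them. Besides Obox6 there were 8 genes within 3 Mb of Crx in the P2 table and 6 in the P21 table. In Crx-/- 5 of these 8 were called at P2, all lower, with changes from -1.01 to -0.38, and 5 of 6 at P21, with 3 higher and 2 lower (limma). No reads were analysed here, so whether the Obox6 transcript starts at its own promoter is not known.

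Klk1b22, a kallikrein gene with many close paralogs and therefore uncertain, split the samples of 1 genotype at P2. It was listed at 0 in wild-type replicate 1 and at 22.5 FPKM in wild-type replicate 2, at 23.1 and 26.8 in CrxRip/+, and at 0 in the 6 samples of the other genotypes. The interferon-induced genes Mndal and Ifi203, which are neighbours in a family of close paralogs, were at 6.9 and 5.3 FPKM in CrxRip/Rip replicate 1 and at 1.3 and 0.3 in replicate 2, and at 3.8 and 2.8 in CrxRip/+ replicate 1 and 0.2 and 0.1 in replicate 2.

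In Nrl-/- at P2 the Polycomb methyltransferase gene Ezh2 was at 13.4 ± 0.28 FPKM against 45.6 ± 1.06 in wild type, a called change of -1.69 (limma, adjusted p = 7.00e-06) that was -0.68 after rescaling by the median of ratios. The clock genes Per2 (5.1 ± 0.57 against 1.9 ± 0 FPKM) and Gm129 (6.55 ± 0.21 against 1.25 ± 0.07 FPKM) were higher in the same samples, by 1.07 and 1.75 (limma, largest adjusted p = 7.80e-05), with Per2 at 1.93 after that rescaling. The hour at which retinas were collected is not given in the sources used here.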
